A study of Mus musculus with 3 samples.

How the data were processed

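The series measured RNA of single cells from mouse cochlea in 3 samples, control, HHL and NIHL, each 1 library made from 6 mice. The deposited file holds UMI counts per gene and cell barcode that Cell Ranger 7.1.0 wrote, per the file headers. The genome build is GRCm39, per the submitters' processing notes, and the libraries are 10x 3′ gene expression libraries, per the labels' protocols. The settings for calling cells and for pooling the libraries are not given in the sources used here. The counts are whole numbers from 1 to 17353, and the lowest total of a barcode was 501, 500 and 500 UMIs in libraries 1, 2 and 3. Of the 32285 gene identifiers, 32158 were found in the reference table of gene names, 31436 with the same symbol. Names are those of the deposited file, and 78 genes share a symbol with another gene.

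All cells stand in 1 table, and the numeric suffix of a barcode (1, 2 or 3) matches no sample label. The libraries were therefore numbered by suffix, put into no group and not compared as control, HHL and NIHL. A group was not inferred from the order of samples or from any value. Values are given per library, with no test and no p-value, since each library is 1 sample and cells are not replicates. Shares of cells have exact Clopper-Pearson 95% intervals, with a floor of 3 counts where a share is 0, and summed UMIs exact Poisson 95% intervals, which cover counting error alone and not differences between mice, dissections or libraries.

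Barcodes with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 16883, 9602 and 10703. The mitochondrial maximum was passed by 814, 313 and 632 barcodes, and 387, 185 and 38 had under 200 genes. Doublets were called per library with scrublet in scanpy 1.11.5 at an expected rate of 6% and left out: 1036 (6.14%), 536 (5.58%) and 506 (4.73%). Counts were scaled to 10000 per cell and put on a natural log scale. The 2000 most variable genes among those seen in at least 10 cells gave 30 principal components, 15 nearest neighbours and shared-neighbour weights, and Leiden clusters at resolution 1.0 with python-igraph 0.11.9. No batch correction was made, so a cluster held mostly by 1 library may be that library and not a cell type. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (TMM factors only) were used.

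The filters, 38 lists of cell type markers, 22 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The exact rule that turns markers into names was not. It was set after the clusters and their cells per library had been seen, and 3 naming rules were tried in all. The rule used names a cluster after the list with the highest mean log2 fold against all other cells, if at least 3 markers making up 50% of the list were in at least 10% of the cells with a log2 fold over 1, and the mean log2 fold was at least 1. A cluster stayed unnamed if its 10 leading genes held more markers of another list, or if its median depth was under 1/3 of the library's median with no own marker among the leading genes. Of 43 main clusters, 14 of cochlear character (3824 cells) were split further at resolution 2.0 into 39 sub-clusters. This step too was chosen after seeing the data, as was merging the names cochlear fibrocyte and strial basal cell into 1 class. Sub-clusters with at least 2 blood markers among the 10 genes that set them off from other cochlear cells were kept out of the classes as mixed. Of the 29 main clusters of blood 25 had a name, and of the sub-clusters 26 had a name, 5 were mixed and 8 stayed unnamed. Names therefore mean a cell like that type, and the genes that named a class are not reported as findings about it.

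Raw UMIs were summed per library and class and given as CPM. The 16 named classes with at least 50 cells in every library, of 23 named classes, were compared between libraries. Per library, the log2 ratio of each gene's CPM to the geometric mean of the other 2 libraries was taken, with a count of 0 set to a floor of 3 counts. The ratios of a gene sum to 0 over the 3 libraries, so a rise in 1 library lowers the ratios of the others. A list with at least 3 members of at least 20 summed UMIs was called above or below in a class where its median passed log2 of 1.5, and its median was ranked among 10000 random lists drawn from 20 bins of like expression. Genes named are, first, up to 4 members per list and class, those with the highest CPM or the largest ratio between libraries, with naming markers of the class left out of that ranking, which was added to the fixed rule after the values were seen. Second, for the 2 classes described in full, they are the 10 genes with the largest ratio of highest to lowest library among genes with at least 50 CPM in 1 library and 50 summed UMIs. Last, they are the markers behind a class name. Leading genes of a cluster are named where the cluster is discussed. Which classes were described in full, and the shares and lists led with (cochlear, erythroid and neutrophil shares, and the interferon, heat shock, mitochondrial, granule and antigen presentation lists), were chosen after their values were seen. Some members of the fixed lists and some naming markers are not reported here and are left out of the text and figures, though they count in the lists and names. Levels of the sex-linked genes were left out, and that list is given as counts.

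The ratios were tested on simulated data, drawn from the real class profiles with 200 genes changed by known folds in library 3. All simulated libraries of a class shared 1 profile and otherwise differed by counting error alone. Calls of unchanged genes therefore do not cover differences between libraries in clusters, free RNA or doublets. A gene was called where it was at least 1.5-fold past both other libraries, and list medians were not simulated. In neutrophil-like cells (2356 genes run, raised only), 0% of genes raised 1.5-fold and 100% of those raised 2-, 3- or 5-fold were called, and 0% of unchanged genes, which shifted by −0.15 on the log2 scale. In endothelial-like cells (4164 genes run), 22%, 94%, 100% and 100% were called, and 1.87% of unchanged genes, with a shift of −0.09. With genes both raised and lowered, the shifts were −0.05 and −0.04 (2373 and 4190 genes run). At 1.5-fold, 8% of raised and 68% of lowered genes were then called in neutrophil-like cells and 40% and 32% in endothelial-like cells. At 2-fold the calls were 100% and 100% and 92% and 88%, and at 3- and 5-fold 100% in both. TMM scaling moved the median of all genes of a class by −0.51 to 0.01 in library 1, −0.04 to 0.23 in library 2 and −0.08 to 0.28 in library 3 on the log2 scale, by more than 0.1 in 8, 3 and 4 classes.

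The alternatives were all barcodes as deposited, a mitochondrial maximum of 10%, a minimum of 1000 UMIs, doublets kept, resolutions of 0.5 and 2.0, 20 components, 4000 variable genes, erythroid cells left out of the denominator, TMM factors, totals without hemoglobin and mitochondrial genes, cells thinned to 1000 UMIs, a minimum of 100 summed UMIs and a minimum of 200 CPM. Added after seeing the data were the 2 earlier naming rules, sub-clusters at resolution 1.0 and single clusters in place of classes. RNA outside cells was measured and not removed. Raw reads, spliced and unspliced counts and trajectories were not analysed here.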

Results

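Single-cell 3′ RNA sequencing was made from cochleae of C57BL/6J mice in 3 groups: control without noise, HHL (hidden hearing loss, 110 dB for 2 h) and NIHL (noise-induced hearing loss, 115 dB for 4 h over 3 days). Cochleae were taken 6 h after the last exposure, and each group has 1 library from 6 mice. The design asks how cochlear cells differ after a mild and a severe noise exposure. The cells of all 3 libraries stand in 1 table of UMI counts, in which a barcode suffix separates the libraries. No label or file ties a suffix to a group, so the libraries are called library 1, 2 and 3 after their suffix, and control, HHL and NIHL were not compared. With 1 library per group there are no replicates, no test was run, and every interval given is a 95% interval for counting error alone.

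A UMI was counted for 24657 genes, and the table held 371949361 UMIs in all. Libraries 1, 2 and 3 had 17720, 10028 and 11344 barcodes with 132576349, 93048140 and 146324872 UMIs. After the filters and the removal of called doublets, 15847, 9066 and 10197 cells were left. Their median depth was 5166 (5073 to 5276), 6046 (5932 to 6185) and 7868 (7651 to 8074) UMIs per cell, and their median share of mitochondrial UMIs was 2.99%, 2.19% and 2.90%. The median number of genes per cell was 1899, 1803 and 2361. With each cell thinned to 1000 UMIs it was 548, 549 and 604, with 253, 263 and 373 shallower cells left out.

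The suspensions were dominated by blood-forming and immune cells, and all other cells, called cochlear here, were the smaller part in each library. The cochlear compartment thus takes in cells not of the cochlea proper, such as osteoblast-like, middle ear epithelium-like and unnamed stromal cells. Blood cell classes made up 92.4%, 88.8% and 84.2% of the cells of libraries 1, 2 and 3. Cochlear classes made up 6.80% (6.42 to 7.21), 10.3% (9.67 to 10.9) and 14.5% (13.8 to 15.2), which is 1078, 933 and 1481 cells. Cells like neutrophils, immature neutrophils, monocytes and granulocyte-monocyte progenitors were the bulk of the blood compartment. Each class name rests on markers fixed beforehand and means a cell like that type.

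Among the named classes, the libraries differed most in percentage points in the immature neutrophil, neutrophil and erythroid classes (m marks a main cluster). Some small classes differed more by ratio than neutrophil-like cells. Erythroid-like cells, named from hemoglobin genes and Alas2, made up 0.593% (0.480 to 0.725) of library 1, 15.3% (14.6 to 16.1) of library 2 and 8.44% (7.91 to 9.0) of library 3. Neutrophil-like cells, named from S100a8, S100a9, Retnlg and Cxcr2, made up 27.9% (27.2 to 28.6), 29.3% (28.3 to 30.2) and 14.2% (13.5 to 14.9). Immature neutrophil-like cells (Ngp, Camp, Ltf) were at 26.7% (26.1 to 27.4), 8.57% (8.0 to 9.17) and 14.6% (13.9 to 15.3). They include the shallow cluster m30 (38, 53 and 215 cells), with a median depth of 0.13 of the library's median. Macrophage-like cells (C1qa, Csf1r, Mrc1) were at 2.10% (1.88 to 2.34), 3.51% (3.14 to 3.91) and 5.73% (5.28 to 6.20), monocyte-like cells at 11.5%, 9.45% and 11.4%, and granulocyte-monocyte progenitor-like cells (Elane, Mpo) at 8.61%, 4.38% and 7.79%. Mature B-like cells made up 1.07%, 1.51% and 2.76%, T-like cells 1.69%, 2.69% and 1.92%, and plasmacytoid dendritic-like cells 1.55%, 0.761% and 1.0%. With called doublets kept, neutrophil-like cells were 20.2%, 24.1% and 15.4%, and under the first naming rule tried they were 5.59% of library 3. Erythroid-like cells were 0.940%, 17.4% and 11.9% with 4000 variable genes and 0.953%, 18.5% and 12.95% under the first naming rule. The unnamed blood clusters m14, with the erythroid genes Klf1, Ermap, Car1 and Car2 among its leading genes, and m24, led by Car1, held 57, 285 and 460 and 5, 118 and 278 cells, which are not counted as erythroid-like here.

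**Figure D1:**
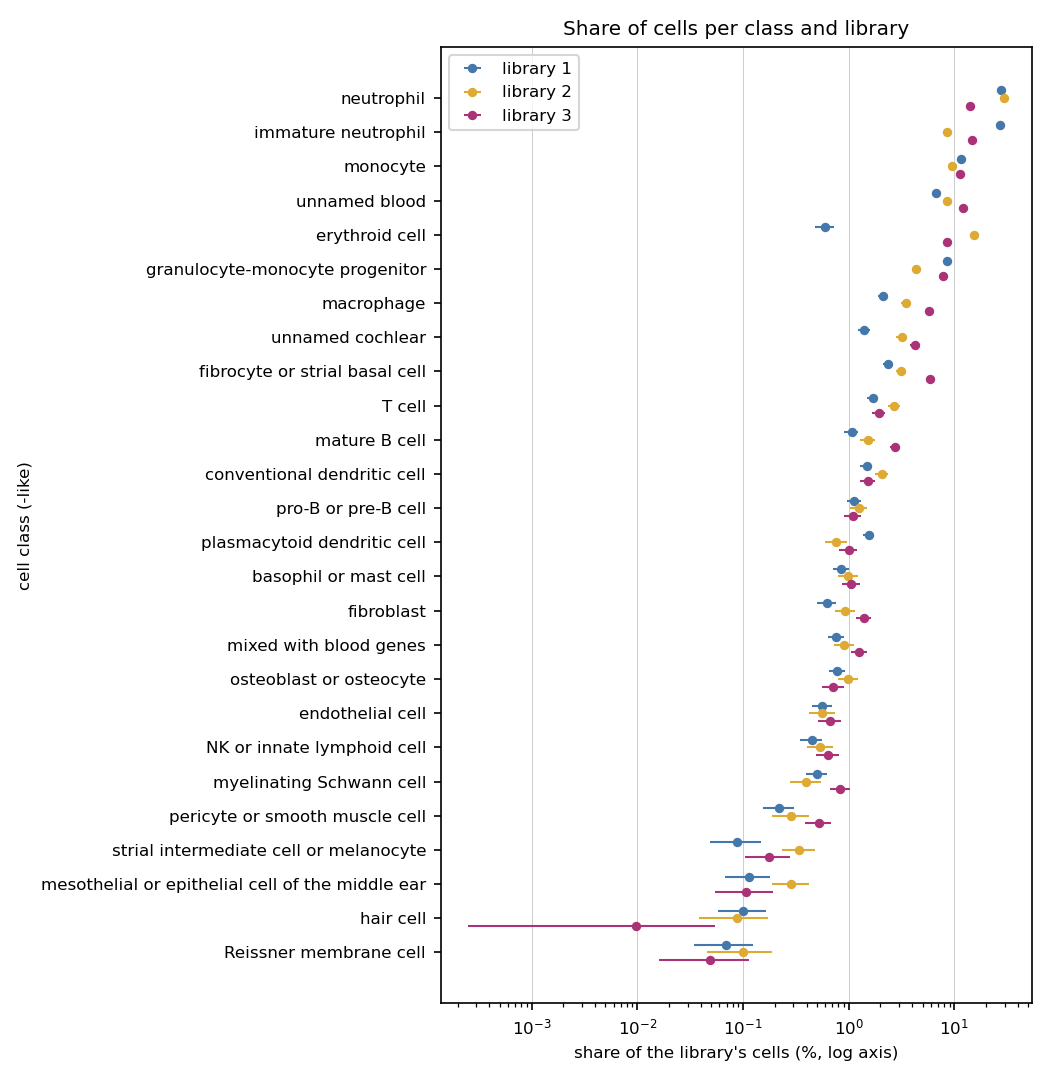
Share of each library's cells (percent, log axis) per cell class, for the 3 libraries, with exact 95% intervals that cover counting error alone. Erythroid-like cells range from 0.593% in library 1 to 15.3% in library 2, and hair cell-like cells from 1 cell in library 3 to 16 cells in library 1.

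Among the cochlear cells, fibrocytes and strial basal cells were the largest named class, and sensory and strial epithelial cells were few. Fibrocyte or strial basal cell-like cells (Coch, Otos, Otor, Cldn11) numbered 374, 284 and 596, or 34.7%, 30.4% and 40.2% of the cochlear cells. Fibroblast-like cells (Dcn, Lum, Col3a1) numbered 98, 84 and 142, osteoblast or osteocyte-like cells (Bglap, Ibsp, Dmp1) 123, 90 and 73, and myelinating Schwann-like cells (Mbp, Prx) 79, 36 and 85. Endothelial-like cells (Cldn5, Cdh5, Flt1) numbered 89, 51 and 68, and pericyte or smooth muscle-like cells (Rgs5, Acta2) 35, 26 and 53. Strial intermediate cell or melanocyte-like cells (Dct, Tyr, Kcnj10) numbered 14, 31 and 18, Reissner membrane-like cells (Vmo1, Slc26a7) 11, 9 and 5, and middle ear epithelium-like cells 18, 26 and 11. Hair cell-like cells (Otof, Slc17a8, Tmc1) numbered 16, 8 and 1, or 0.101% (0.0577 to 0.164), 0.0882% (0.0381 to 0.174) and 0.00981% (0.000248 to 0.0546) of all cells. No cluster met the rule for spiral ganglion neurons, strial marginal cells or supporting cells of the organ of Corti. Cochlear clusters left without a name held 1.39%, 3.18% and 4.21% of the cells, blood clusters without a name 6.73%, 8.49% and 12.1%, and sub-clusters that mixed cochlear with blood genes 0.764%, 0.904% and 1.27%.

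Several classes were held by different clusters in different libraries, so a class value is partly a value of its clusters (s marks a sub-cluster). Monocyte-like cells of libraries 1 and 2 lay mainly in cluster m4 (79.4% and 89.7%), and those of library 3 in cluster m6 (88.9%), which Saa3, Cxcl10, Tnf and Il6 led. Neutrophil-like cells of library 3 lay mainly in m5 (60.6%), led by Il1b, Acod1 and Cxcl2, which held 13.7% and 22.8% in libraries 1 and 2. Immature neutrophil-like cells lay in m1 in libraries 1 and 2 (72.5% and 69.8%) and in m13 in library 3 (50.8%). Fibrocyte or strial basal cell-like cells of library 1 lay mainly in sub-cluster s4 (51.3%), led by Slc7a11, Ccl7, Mt2 and Cxcl1, and those of libraries 2 and 3 in s1 (42.6% and 41.6%). Osteoblast-like cells lay in s8 in libraries 1 and 2 (50.4% and 67.8%) and in s26 in library 3 (49.3%), and erythroid-like cells in m10 in libraries 1 and 2 (75.5% and 61.9%) and in m15 in library 3 (58.5%).

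RNA outside cells reached every class. Hbb-bs, a hemoglobin gene, had a UMI in 20.2%, 100% and 98.5% of endothelial-like cells of libraries 1, 2 and 3, at 152, 5611 and 828 CPM and a median depth of 6328, 5240 and 8604 UMIs. In erythroid-like cells the share was 100% in each library, at 7503, 7196.5 and 8490 UMIs per cell. S100a8, a neutrophil gene, had a UMI in 98.9%, 96.1% and 100% of endothelial-like cells, at 8392, 5815 and 5082 CPM. In library 1 it was at 1444 CPM in fibroblast-like and 14640 CPM in mature B-like cells, at median depths of 2727.5 and 2509 UMIs. RNA outside cells would bring like amounts to classes of like depth. The S100a8 levels are thus not a measure of it alone, and the rest was not tested. Levels of hemoglobin, granule and immunoglobulin genes in other classes therefore hold this background to an unknown extent. The list of 6 free-RNA genes lay above the other libraries in 0, 10 and 2 of 16 classes for libraries 1, 2 and 3 and below in 3, 1 and 3.

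Genes tied to hearing were read per cell class over the 3 libraries summed, with no test between classes. Hair cell-like cells held the calcium-binding protein gene Cabp2 at 1055 (931 to 1191) CPM and the tip-link gene Pcdh15 at 197 (146 to 261). The calcium channel gene Cacna1d was at 165 (118 to 224) CPM and Ctbp2, with the ribbon protein among its products, at 133 (91.5 to 187). Strial intermediate-like cells had the sodium-potassium pump gene Atp1b1 at 5858 (5653 to 6069) CPM, the ion cotransporter Slc12a2 at 1801 (1688 to 1920) and the connexin Gjb6 at 746 (674 to 823). In Reissner membrane-like cells the pump genes Atp1b1 and Atp1b2 were at 630 (538 to 734) and 500.2 (418 to 594) CPM. Fibrocyte or strial basal cell-like cells had the connexin Gjb2 at 247 (236 to 259) CPM and the cartilage-type collagen genes Col11a1 at 253, Col11a2 at 211 and Col2a1 at 190.

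Genes of matrix, myelin, ion transport and vessels were read in the other classes in the same way. Osteoblast or osteocyte-like cells had Col11a1 at 5772 (5686 to 5858), Col11a2 at 3367 and Col2a1 at 3241 CPM, genes in which variants cause deafness. Myelinating Schwann-like cells had the myelin gene Pmp22 at 7809 (7613 to 8010) CPM, which was not among their naming markers, and the potassium channel gene Kcna1 at 1607 (1518 to 1699). Pericyte-like cells had Atp1b1 at 379 and Atp1b2 at 373 CPM. Endothelial-like cells had the leukocyte adhesion genes Vcam1 at 992 (948 to 1037) and Icam1 at 425 (396 to 455), the glucose transporter Slc2a1 at 410 (382 to 440) and the tight-junction gene Tjp1 at 297 (273 to 322). These values pool s10 (125 cells), with Plvap and Stab2 among its leading genes, and s17 (83 cells), with Abcb1a and Slc2a1. Whether both are vessels of the blood-labyrinth barrier was not tested. Macrophage-like cells had Vcam1 at 2098 (2068 to 2128) CPM.

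**Figure D2:**
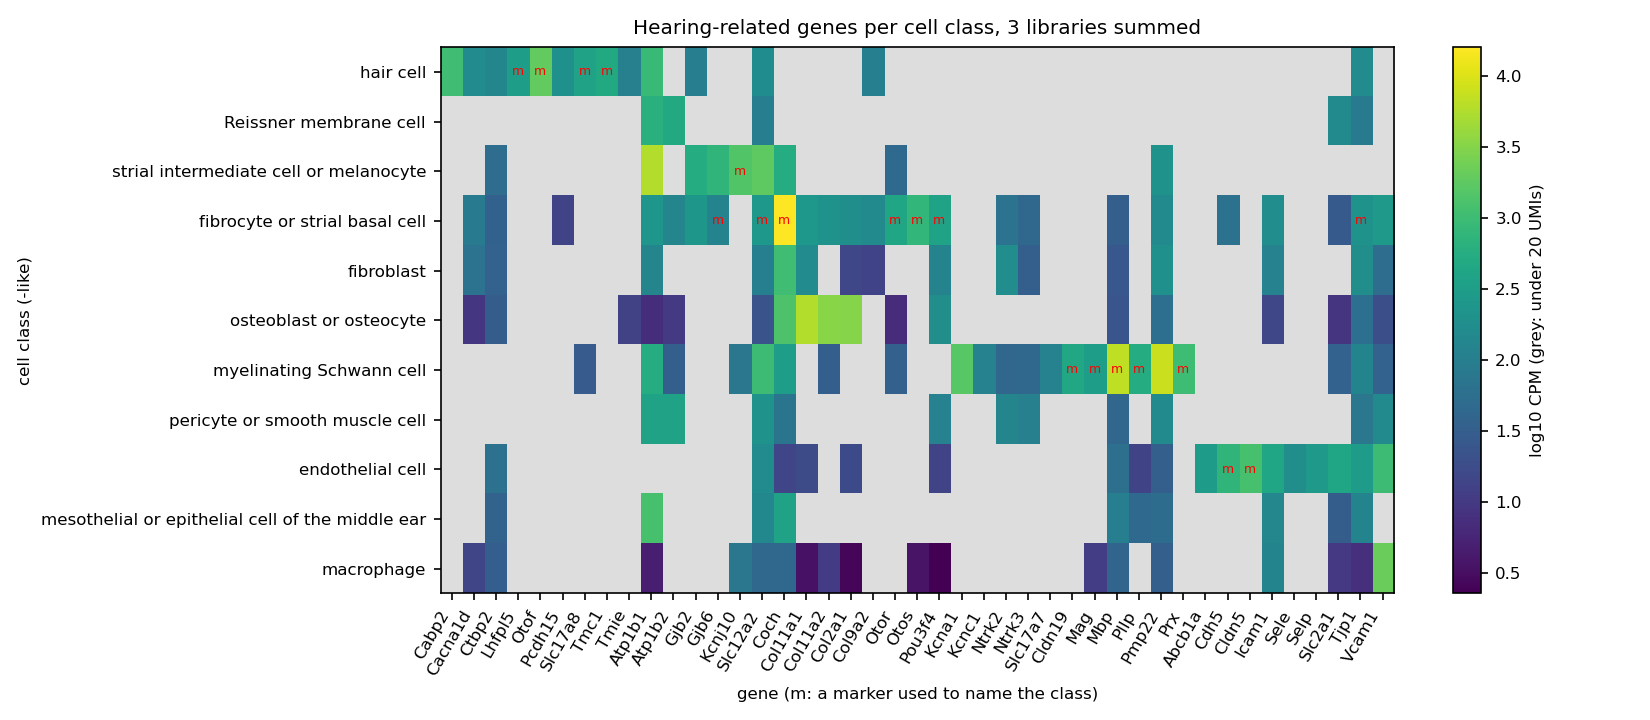
CPM (log10 colour scale) of the reported members of the 6 hearing-related lists with at least 100 CPM in 1 of the classes shown, per cell class, 3 libraries summed; grey marks under 20 UMIs and m a marker used to name the class. Atp1b1 reaches 5858 CPM in strial intermediate-like cells and Cabp2 1055 CPM in hair cell-like cells.

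Fibrocyte or strial basal cell-like cells differed between libraries in ion-transport and stress genes. The connexin gene Gjb2 was at 366, 464 and 53.1 CPM in libraries 1, 2 and 3. The pump gene Atp1b1 was at 173, 446 and 142 CPM. The metallothionein genes Mt1 and Mt2 were at 2054, 1084 and 651 and at 919, 242 and 140 CPM, and the protease inhibitor gene Timp1 at 115, 27.0 and 6.94 CPM. Heat shock genes went the other way: Hspa1a was at 38.3, 97.7 and 549 CPM and Hspa1b at 29.8, 53 and 289 CPM. Some of these genes were leading genes of sub-clusters uneven between libraries: Gjb2 was among the leading genes of s25 and s39, which held 35, 19 and 4 and 8, 9 and 2 cells, Mt2 led s4 (192, 4 and 30 cells), and Hspa1a led s28 (0, 0 and 53 cells). The heat shock list was also higher in library 3 inside s3, at a median of 1.07 (0.888 to 1.20), and s6, at 0.583 (0.359 to 0.729), of this class.

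The 10 genes of this class with the largest ratio of highest to lowest library were Saa1, Prg4, Lypd2, Ucma, Fxyd2, 5430419D17Rik and 4 hemoglobin genes. Saa1, an acute-phase gene, had 6, 144 and 0 UMIs, a ratio of library 2 to library 3 of 76.7 with the 0 set to the floor of 3 counts. This ratio has no interval, and the 0 UMIs of library 3 allow up to 1.11 CPM against 69.3 CPM in library 2. Prg4, which encodes lubricin, was at 137, 226 and 3.62 CPM, a ratio of 62.5 (35.5 to 122), and Lypd2 at 52.2, 59.7 and 2.41 CPM. Ucma, a matrix gene of cartilage, was at 204, 121 and 9.35 CPM, the pump modulator Fxyd2 at 485, 585 and 28.0 CPM, and 5430419D17Rik at 63.8, 36.1 and 3.62 CPM. Ucma and Fxyd2 were leading genes of s25 and s39. Hbb-bt, Hba-a2, Hbb-bs and Hba-a1 were 34.5, 34.0, 33.6 and 27.2 times as high in library 2 as in library 1, and mark erythroid cells.

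Neutrophil-like cells of library 3 had higher levels of interferon genes and of the chemokine and cytokine list than those of libraries 1 and 2. The medians of the chemokine and cytokine list were −0.68, 0.11 and 1.21 in libraries 1, 2 and 3. Of the 10 genes with the largest ratio, 4 were highest in library 3: Lipg, a lipase gene, at 4.31, 1.52 and 58.7 CPM, a ratio of 38.7 (23.2 to 69.9), Ifit3 at 13, 9.80 and 135 CPM, a ratio of 13.8 (11.2 to 17.2), Wfdc17 at 210.2, 377 and 2588 CPM, a ratio of 12.3 (11.9 to 12.8), and the guanylate-binding protein gene Gbp2 at 42.9, 22.5 and 251 CPM, a ratio of 11.1 (9.67 to 12.9). The other 6 were highest in library 2 and mark erythroid cells: Hba-a2, Hbb-bs, Hbb-bt, Slc4a1, Hba-a1 and Car2, with ratios of 28.1, 26.1, 25.7, 22.9, 22.5 and 15.9. The neutrophil chemoattractant gene Cxcl2 was at 402, 275 and 1276 CPM, Cxcl10 at 22.3, 10.2 and 95.4 CPM and the cytokine gene Il1b at 826, 1504 and 2065 CPM, where library 3 was under 1.5 times library 2. Il1b and Cxcl2 were among the leading genes of m5.

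Interferon response genes were higher in library 3 than in libraries 1 and 2 in nearly every class. Over 16 classes, the median log2 ratio of this list of 10 genes to the geometric mean of the other 2 libraries was at least log2 of 1.5 in 15 classes for library 3, and in 0 classes for libraries 1 and 2. It ranged from 0.91 in fibroblast-like cells to 3.23 in immature neutrophil-like cells, at 1.94 in neutrophil-like, 1.93 in macrophage-like, 2.20 in endothelial-like and 2.25 in osteoblast-like cells. In each of the 15 classes the median lay above 100% of 10000 random lists matched on expression. The median lay below the other libraries in 7 classes for library 1 and in 15 for library 2. These counts in part restate the rise of library 3, since the ratios of a gene sum to 0 over the libraries.

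Single interferon genes were highest in library 3 in most of these classes. In macrophage-like cells Irf7, the transcription factor of the type I interferon response, was at 84.1 (70.2 to 99.9), 85.1 (74.3 to 97.2) and 514 (494 to 534) CPM. Isg15, a ubiquitin-like modifier, was at 87.4, 78.9 and 425 CPM in neutrophil-like cells, at 151 (125 to 180), 87.7 (62.7 to 119) and 584 (528 to 644) CPM in endothelial-like cells and at 28.4, 11.1 and 190.5 CPM in osteoblast-like cells. Ifit1 was at 15, 24.8 and 105 CPM in macrophage-like cells. Fibroblast-like cells were mixed, with the antiviral genes Rsad2 at 345.9, 13.9 and 47.1 CPM and Ifit1 at 249.8, 11.9 and 122 CPM, both highest in library 1. Fibrocyte or strial basal cell-like cells were the 1 class with the list not above in library 3, with a median of −0.61 in library 3: Rsad2, Ifit1 and Ifit3 were at 248, 97.3 and 31.7, at 546, 590 and 160 and at 245, 213 and 108 CPM. Rsad2 and Ifit1 led sub-cluster s19 of this class, which held 54, 17 and 3 cells.

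**Figure D3:**
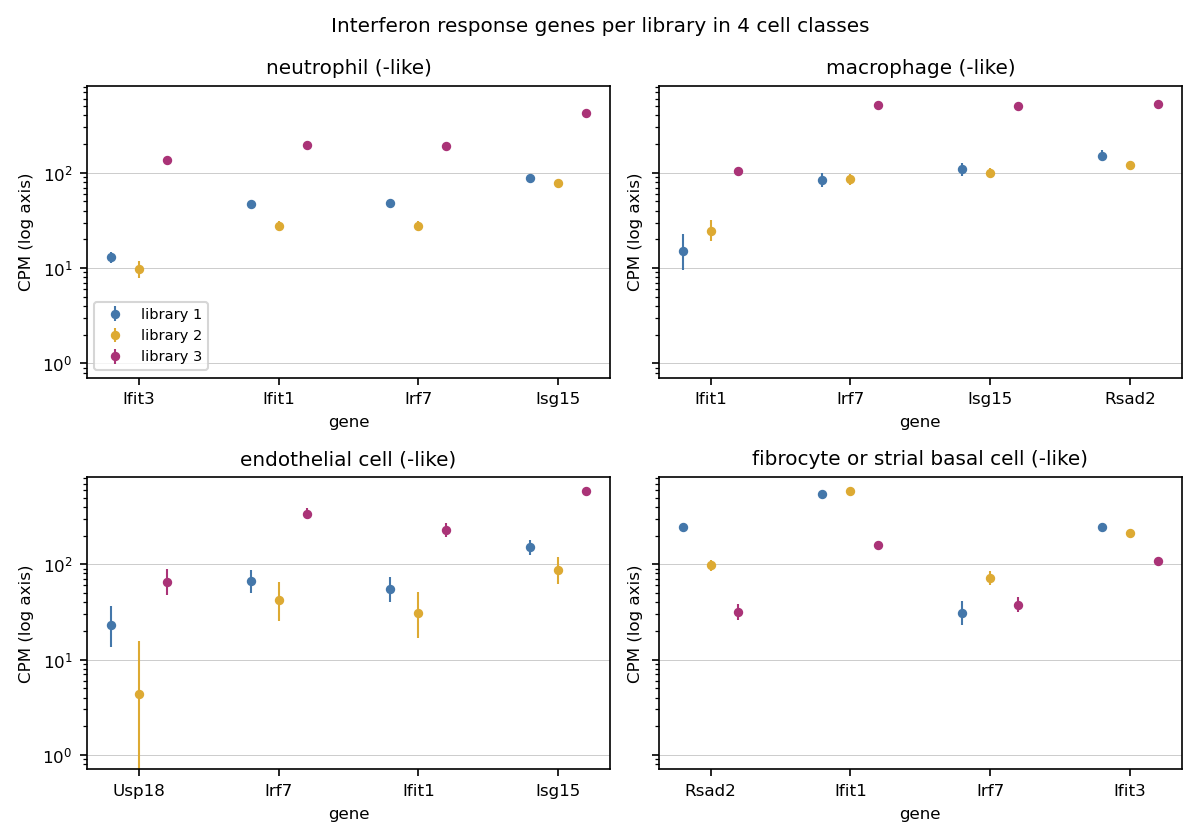
CPM (log axis) of the 4 interferon response genes with the largest ratio between libraries in each of 4 cell classes, for the 3 libraries, with exact Poisson 95% intervals. Isg15 is at 425 CPM in neutrophil-like and 584 CPM in endothelial-like cells of library 3, and Ifit1 at 160 CPM in fibrocyte or strial basal cell-like cells of library 3 against 546 and 590 in libraries 1 and 2.

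Heat shock genes were also higher in library 3, and immediate-early genes were not. The heat shock list lay above the other libraries in 0, 0 and 12 of 16 classes and below in 2, 5 and 0 classes. As for the interferon list, the counts below in part restate the rise of library 3. The heat shock list's median in library 3 was 1.36 in granulocyte-monocyte progenitor-like, 1.26 in osteoblast-like, 1.04 in endothelial-like and 0.85 in fibrocyte or strial basal cell-like cells. In osteoblast-like cells Hspa1a, an inducible chaperone gene, was at 15.5, 34.1 and 451 CPM and the small heat shock gene Hspb1 at 20.7, 7.93 and 363 CPM. In endothelial-like cells Hspa1a was at 89.4, 140.3 and 415 CPM and Hsph1 at 25.5, 19.7 and 157 CPM. The immediate-early list lay above in 0, 0 and 1 classes and below in 0, 2 and 0. That 1 class was osteoblast-like cells, with Atf3 at 283, 105 and 1512 CPM. Atf3 was among the leading genes of s26, which held 14, 7 and 36 of these cells.

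Inflammatory genes were uneven between classes. The chemokine and cytokine list lay above the other libraries in 1, 3 and 7 of 16 classes and below in 5, 5 and 0, and the acute-phase and metallothionein list above in 3, 1 and 5 and below in 3, 6 and 0. In monocyte-like cells Cxcl2 was at 178, 22.4 and 615 CPM, Cxcl10, a chemokine for T cells, at 115, 26.2 and 375 CPM and Tnf at 132, 29.7 and 294 CPM. Cxcl2, Cxcl10 and Tnf were all leading genes of m6. Endothelial-like cells had Cxcl10 at 304, 314 and 1925 CPM, while Cxcl12, which retains blood-forming cells in their niche, was at 2725, 4273 and 606 CPM. The complement list lay above in 1, 2 and 6 of 13 classes and below in 7, 2 and 1. The blood-labyrinth barrier list lay above in 0, 0 and 4 of 15 classes and below in 1, 0 and 0, and in endothelial-like cells its medians were −0.01, −0.12 and 0.29. These medians pool s10 and s17, with 56.2%, 54.9% and 69.1% of the endothelial-like cells in s10.

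Library 1 differed from the others in mitochondrial, granule and antigen presentation genes. Its mitochondrially encoded respiratory chain list lay above the other libraries in 8 of 16 classes (0 and 0 for libraries 2 and 3) and below in 0, 0 and 1 classes. In neutrophil-like cells mt-Co1 was at 4879, 2566 and 2034 CPM, and the list's median in library 1 was 1.10. With TMM factors it lay above in 5 classes. The neutrophil granule and recruitment list lay above in 8, 1 and 1 classes (5 in library 1 with TMM factors) and below in 0, 5 and 6. Granule genes mark neutrophils and may come from the background in other classes. Ltf was at 1699, 215 and 174 CPM in macrophage-like cells, and its source there was not tested. The antigen presentation list lay above in 0, 5 and 3 classes and below in 7, 0 and 0, and below in 3 for library 1 with each cell thinned to 1000 UMIs. Cd74, a gene of antigen-presenting cells, was at 7.76, 99.1 and 104 CPM in osteoblast-like cells and at 160, 454 and 432 CPM in endothelial-like cells.

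The other lists are given without a ranking, since they were measured in different numbers of classes. Counts of classes above, then below, the other libraries are given for libraries 1, 2 and 3. Potassium recycling: 0, 5 and 0 above and 2, 0 and 1 below of 14 classes, with medians of −0.39, 1.05 and −0.97 in fibrocyte or strial basal cell-like cells. Matrix and hearing-loss genes of fibrocytes: 1, 5 and 1 above and 2, 0 and 2 below of 11. Myelin: 6, 0 and 0 above and 0, 2 and 5 below of 9. Schwann-like cells, at 36 in library 2, were too few to be among these classes, so the counts say nothing of myelin genes in Schwann-like cells. Hair cell synapse genes: 1, 1 and 1 above and 0, 0 and 2 below of 6, and auditory neuron genes: 0, 3 and 0 above and 1, 0 and 3 below of 5. The hair cell and neuron genes were measured there in classes other than hair cells and neurons, which had too few cells. Endoplasmic reticulum stress: 3, 0 and 2 above and 0, 3 and 0 below of 16. Glucocorticoid and circadian genes: 2, 0 and 1 above and 0, 1 and 2 below of 16. Cell cycle: 1, 0 and 1 above and 2, 2 and 0 below of 16. The p53 and apoptosis list was above in 0 and below in 0, 1 and 0 of 16, and the oxidative stress defence list was above in 0 and below in 0 of 16 for each library. The sex-linked list was above in 0 classes and below in 3 combinations of class and library.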

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

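Chosen after the results were seen were the 2 earlier naming rules, sub-clusters at resolution 1.0 and single clusters in place of classes. No paired analysis was possible because the groups share only replicate number 1 and no library is tied to a group. Depth limits the small classes: 1 hair cell-like cell in library 3 allows a share of up to 0.0546%. The order of the libraries in the erythroid share (lowest in library 1, highest in library 2) and in the cochlear share held under each alternative run, and library 3 had the lowest neutrophil share under each. The interferon list lay above in library 3 in 14 to 16 classes and the heat shock list in 11 to 13 under 6 alternatives, and in 94.4% and 77.8% of the 18 single clusters, which are all blood clusters. A list with under 3 measured members under a setting has no value there. Of 206 list medians run with a minimum of 100 summed UMIs 177 stayed within their counting interval, of 192 thinned 82, of 255 with doublets kept 160, of 237 with a mitochondrial maximum of 10% 177, of 255 with TMM factors 208, and of 255 with totals without hemoglobin and mitochondrial genes 240. The other medians moved or reversed, and the cause was not tested.

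Among the depths, cell numbers, shares and lists led with, the values that moved are given next. Over all classes and lists more moved: 36 of 87 shares and 42 of 132 counts of classes with doublets kept, and 33 of 87 shares with a mitochondrial maximum of 10%. Mitochondrial maximum 10%: median depth 5286 and 8146 UMIs (libraries 1 and 3), cochlear share 5.90% and 9.63% (1 and 2), neutrophil share 29.2% and 13.3% (1 and 3). All barcodes: 7504 UMIs in library 3. Minimum 1000 UMIs: erythroid share 0.763%, 16.4% and 10.6%. Doublets kept: erythroid 16.6% and 10.1% (2 and 3), neutrophil 20.2%, 24.1% and 15.4%. Resolution 0.5: erythroid 0.782%, 16.4% and 10.3%, neutrophil 30.1% and 19.0% (1 and 3). Resolution 2.0: erythroid 0.764%, 16.4% and 10.2%, neutrophil 27.2% (1). With 20 components neutrophils were 29.3% and 19.6% (1 and 3). With 4000 variable genes erythroid cells were 0.940%, 17.4% and 11.9% and neutrophils 29.5% and 19.6% (1 and 3). First naming rule: erythroid 0.953%, 18.5% and 12.95%, neutrophil 24.1%, 22.6% and 5.59%. Without erythroid cells in the denominator, by construction, cochlear 12.2% and 15.9% and neutrophil 34.6% and 15.5% (2 and 3). The antigen presentation list lay below in 3 classes in library 1 with cells thinned to 1000 UMIs, and with TMM factors the mitochondrial list lay above in 5 classes and the granule list in 5. Of the 160 genes with the largest ratios, 83 were left at a minimum of 200 CPM, which takes fewer genes, and 103 with doublets kept.

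List medians (log2) that reversed follow, with the library in brackets. Doublets kept: complement 1.02 (2) and −0.33 (3) in T cells and −0.072 (3) in osteoblasts, chemokines 0.073 (1) in conventional dendritic and 0.11 (2) in erythroid cells, acute-phase −0.75 (2) in conventional dendritic cells, granule 0.15 (2) in erythroid and −0.18 (3) in pro-B or pre-B cells, antigen presentation 0.040 (1) in granulocyte-monocyte progenitors and −0.060 (2) in osteoblasts, myelin −0.28 (1) in osteoblasts. Mitochondrial maximum 10%: granule −0.39 (2) in conventional dendritic cells, antigen presentation −0.020 (2) in granulocyte-monocyte progenitors, complement 0.12 (1) and −0.14 (3) and myelin −0.41 (1) in osteoblasts. Minimum 100 summed UMIs: chemokines 0.26 (2) in erythroid cells, myelin 0.059 (2) in fibrocytes, potassium recycling 0.49 (1) in immature neutrophils, hair cell synapse −0.085 (2) in monocytes, antigen presentation −0.30 (2) in osteoblasts. Thinned to 1000 UMIs: acute-phase 0.039 (2) and interferon 0.00421 (1) in erythroid cells, cell cycle 0.093 (1) in fibrocytes. With doublets kept, the log2 ratios of Jchain (library 1 over 2) and Igha (3 over 2) in mature B cells turned to −1.36 and −3.25. The cause was not tested.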

Other observations

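Chosen only after the result was seen were the tests of dissociation stress, of free RNA, of single clusters within blood and cochlear classes and of the yield of epithelial cells, and the search for single neurons.

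A few single cells carried the genes of spiral ganglion neurons although no cluster had that name. Cells with at least 5 of the 10 neuron markers numbered 5 (0, 2 and 3 in libraries 1, 2 and 3), and 8 more were 1 marker short, 6 of them hair cell-like. Of the 5, 1 was hair cell-like and 4 lay in the Schwann-like sub-cluster s29. In 3 of these, at 34037, 39734 and 46052 UMIs, Snap25, a gene of vesicle release, had 123, 130 and 145 UMIs and Nefl, a neurofilament gene, 84, 107 and 148. Slc17a7, the glutamate transporter of auditory neurons, had 32, 22 and 35 UMIs. The other cell had 1728 UMIs, with 3 of Snap25 and 1 of Slc17a7. All of the Schwann-like class's Kcnc1 UMIs, 0, 29 and 61 by library, lay in these 3 cells (29, 28 and 33).

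The cochlear sub-clusters s28, s4 and s24 lay mostly in 1 library, so they are not shown to be cell types apart from that library. Fibrocyte-like s28, led by Hspa1a, Tnfaip6 and Hspa1b, had 0, 0 and 53 cells, and 0 cells, at a floor of 3 counts, allow up to 0.0189% and 0.0331% of libraries 1 and 2. Fibrocyte-like s4 (Slc7a11, Dio2, Ccl7, Mt2) had 192, 4 and 30 cells, and unnamed stromal s24, led by Adipoq and the interferon-induced Cxcl9, 4, 2 and 53. Few cells of library 1 lay in fibrocyte-like s1 (Cntn1, Npr3, Col4a3), with 9, 121 and 248 cells, and unnamed s2 (Fst, Dner, Abcc9), with 25, 101 and 218. Unnamed sub-clusters spread over the 3 libraries included stromal s15, led by Adipoq, Lpl and Cxcl12, with 51, 36 and 13 cells. These 3 genes were among the leading genes of s24 too, so s15 and s24 are not shown to be separate cell types. Also spread was 1 unnamed epithelial sub-cluster. This s20, led by Ceacam16, a gene of the tectorial membrane, with Slc26a4 among its leading genes, had 36, 22 and 15. In macrophage-like cells, Ctsk, a protease gene of osteoclasts, had 5, 6 and 703 UMIs, a ratio of library 3 to 2 of 59.9 (27.4 to 164), and Mmp12 19, 247 and 14.

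Interferon response genes lay higher in library 3 in 15 of 16 classes. Free RNA of 1 make-up would bring no more of a gene than other classes hold, scaled by S100a8 and S100a9 or by hemoglobin genes, whichever gave more. With the lowest such bound taken off library 3, the median stayed at log2 of 1.5 or above in 5 of the 9 classes tested. It was 2.00 (1.64 to 2.16) in endothelial-like, 1.60 (0.968 to 2.01) in osteoblast-like and 1.29 (0.809 to 1.65) in plasmacytoid dendritic-like cells. It was 0.924 (0.681 to 1.10) in conventional dendritic-like and 0.802 (0.0972 to 1.24) in pro-B or pre-B-like cells. The intervals leave out the error of the bound, and these classes were set apart after their values were seen. The values argue against free RNA as the whole source there only if the scaling genes measure free RNA alone. That is not certain, since S100a8 and S100a9 ranged from 2852 CPM in osteoblast-like to 27293 CPM in mature B-like cells of library 3. T-like and endothelial-like cells had S100a8 and S100a9 at 10848 and 10028 CPM and hemoglobin genes at 1188 and 1128 CPM, and an excess of the list of 364 and 4704 CPM. In the other 4 it stayed in 0, at 0.277 (−0.364 to 0.447) in T-like, −2.21 (−2.82 to −1.8025) in mature B-like, −2.83 (−3.24 to −2.31) in basophil or mast-like and 0.429 (0.104 to 0.611) in fibroblast-like cells, from 1.26, 2.34, 1.804 and 0.909 before. In T-like, mature B-like and basophil or mast-like cells free RNA and expression thus cannot be told apart, because the bound takes all of a class's RNA of these genes as free. The mature B-like and basophil or mast-like medians were set by the floor of 3 counts and are not measured levels. In fibroblast-like cells a part beyond the bound was left. Over the 9 classes the excess did not rise with S100a8 and S100a9, with a rank correlation of −0.283. The test asked for at least 0.8 if free RNA was the whole source, a cut set after the values were seen. Since S100a8 and S100a9 may not measure free RNA alone, this correlation cannot decide the question. With the bound from fibrocyte or strial basal cell-like cells alone, which make these genes themselves, 0 of the 9 stayed. Different clusters within a class were argued against as the whole source too. In blood classes of several clusters, 12 of 13 single clusters with at least 50 cells in every library had the higher list. In endothelial-like, fibroblast-like and osteoblast-like cells, 5 of 5 sub-clusters with at least 20 cells in every library had it, at medians of 0.733 (0.542 to 1.20) in fibroblast-like s5 to 2.45 (2.04 to 2.51) in endothelial-like s17. Osteoblast-like s8 and s26 and fibroblast-like s31 had too few cells for this, as had several blood clusters, among them m13 and m15. In library 3, m13 held 50.8% of immature neutrophil-like and m15 58.5% of erythroid-like cells, so what they add stays open. The classes that make S100a8 and S100a9 or hold hemoglobin RNA of their own were not tested for free RNA. A state of library 3, be it from its mice, its handling or its exposure, may be behind the rest, and no biological explanation was tested because no library is tied to a group.

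Heat shock genes lay higher in library 3 in 12 of 16 classes. General dissociation stress would raise immediate-early genes too, and these lay above in 1 of the 12 classes. Different clusters within a class were argued against as the whole source in blood classes of several clusters, where 10 of 12 single clusters had the higher list. In endothelial-like and osteoblast-like cells, 3 of 3 sub-clusters with at least 20 cells in every library had it. They were s10 and s17, at 0.926 (0.767 to 1.06) and 1.19 (0.999 to 1.58), and osteoblast-like s14 at 0.746 (0.590 to 1.03). Since s10 and s17 hold all endothelial-like cells, different clusters were argued against as the whole source there. Osteoblast-like s26 and s8, with 36 and 6 cells in library 3 against 31 in s14, had too few cells in a library for this. So had m13, which held 50.8% of the immature neutrophil-like cells of library 3, and what it adds stays open. The median of the whole osteoblast-like class was 1.26, so part of its difference lay within s14, and how much the mix of sub-clusters adds stays open. In fibrocyte or strial basal cell-like cells 1 of 2 had it, s3 at 1.07 (0.888 to 1.20), with s6 at 0.583 (0.359 to 0.729), just under log2 of 1.5. Part of the difference thus lay within clusters there, and how much s28, in library 3 alone, adds to it stays open. A difference in temperature or time at preparation may still be the source, and was not tested, and no biological explanation was tested.

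Hair cell-like cells numbered 16, 8 and 1. If library 3 had yielded fewer epithelial cells of every kind, hair cell-like cells would make up a like share of the epithelial clusters, and they made up 19.8% (11.7 to 30.1) of 81, 12.3% (5.47 to 22.8) of 65 and 3.125% (0.0791 to 16.2) of 32 cells. The intervals overlap, which does not show that the shares are alike, and the epithelial cells include those of the middle ear. With these counts and 1 library per group, a lower yield and a loss of hair cells cannot be told apart. No biological explanation was tested.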
